A study of Mus musculus with 27 samples.

How the data were processed

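RNA was measured by SMART-seq2 and 150 bp paired-end sequencing on an Illumina NovaSeq in 27 libraries of DAT+ cells sorted from 3 regions at 3 ages of C57/BL6 mice, with 3 libraries per group. The P60 libraries of NAc and SNc are numbered 1, 3 and 4. Per the labels the design used 5 mice per age, without pairing mice and libraries. The submitters' processing notes name HISAT2 and GRCm38/mm10. The read counter, the annotation and any filters are not given in the sources used here.

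The deposited table holds FPKM for 54532 genes in 26 of the 27 libraries. In VTA P30 replicate 3 the deposited values are in another unit, proportional to FPKM with a divisor of 186473 reads. Multiplied by gene length in kb, its values sum to 55601698, against 670534 to 948735 in the other libraries. The deposited gene length column, in another unit (bases), was used to recover reads: among values below 1000 reads, 100% were whole reads within a tolerance of 0.02 with the length of their own row, against 4.06% with that of the next row and 3.89% with shuffled lengths. The table lacks the capital letter M throughout, and its name column is shifted by a row from row 445, so that 443 names match their gene ID. Symbols were therefore taken by gene ID from the reference annotation, for 54409 IDs, with 123 unmatched. Of the IDs, 54495 are in GENCODE M21 (GRCm38/mm10), and 53411 have the length of its union of exons.

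Each library was rescaled to its reads in genes: the FPKM was divided by the library's sum of FPKM times length in kb, so that this sum is the same in each library. This departs from the plan, which took values as deposited, and was chosen because of VTA P30 replicate 3. The deposited scale is an alternative. Genes with a rescaled value of at least 1 in at least 3 libraries were kept, 18888 in number. limma 3.58.1 (lmFit, and eBayes with trend and robust, in R 4.3.3 with statmod 1.5.0) was fitted to log2(value + 1) of all 27 libraries with a term per group, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Fold changes on this scale understate genes with low values. The 25 comparisons were 6 averaged over regions or ages, 18 between 2 groups, and the region by age interaction. Differences between regions of the P60 vs P7 change came from the same fit. Values are given as mean ± SD, fold changes as log2 fold change ± SE. Voom ran on the recovered reads as an alternative. The other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

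Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Fry ran on the same lists and is not reported, since it does not compare a list with other genes. Of 33 lists fixed before the data were examined, 32 had a member that passed the filter. The ambiguous symbol Atp5o was left out, and an outdated symbol was read by its current name. A further 6 lists of microglial and macrophage states were added after levels of these genes were seen. The count "adjusted over the list alone" adjusts the members' p-values within their list.

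Genes to be named were chosen by a rule fixed before the data were examined. For each averaged comparison the rule took genes past the threshold, with the same direction in all 3 strata, a mean of at least 5 and a symbol that is not a predicted gene, a RIKEN clone or a pseudogene, and named the 10 with the largest increase and the 10 with the largest decrease, up to 4 members with the smallest adjusted p of each list that was called or had at least 3 members past the threshold, and Slc6a3, Th, Slc18a2, Ddc and Nr4a2 always. For comparisons of 2 groups it took the 2 largest in each direction, and for the interaction the 10 smallest adjusted p. Genes without a symbol were left out, which put Lrp8os2 in place of an unnamed gene. Some genes that the rule chose are not named in the text or drawn. Cell type markers in the account of the sort and Pitx3 were chosen after their values were seen.

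A floor of 3 reads gives the value below which a gene counts as not detected. Alternatives were other filters, a pseudocount of 0.1, quantile normalization, the replicate number as a block, a fit of the compared libraries alone and a fit without each library in turn, all chosen before the data were examined, and, chosen afterwards, the deposited scale, voom with sample weights on recovered reads, and a fit without 4 libraries (VTA P30 replicate 3, NAc P60 replicate 3, SNc P60 replicate 3 and VTA P60 replicate 2). These 4 were picked for few detected genes or little 18S rRNA. SNc P30 replicate 1, with 12437 detected genes, was not among them. Fits without a library kept the same genes in the test. A group left with fewer libraries is assumed to vary like the others. Fits were run on 100 random splits of the libraries for averaged comparisons and on all 10 for comparisons of 2 groups. Tested on simulated data with 50 changed genes, the P60 vs P7 comparison gave 2 false calls of 18888 genes. NAc P60 vs NAc P7 gave 3. Camera found a changed list and called 1 of 100 unchanged lists. The proteomic part of the study is not in the series and was not analysed.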

Results

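The series set out to follow the development of DAT+ dopaminergic neurons, cells that carry the dopamine transporter, in 3 brain regions of C57/BL6 mice. RNA was measured in 27 SMART-seq2 libraries of cells isolated by flow cytometry. They came from the nucleus accumbens (NAc), the substantia nigra pars compacta (SNc) and the ventral tegmental area (VTA). The ages were postnatal days 7, 30 and 60 (P7, P30 and P60), with 3 libraries in each of 9 groups. Values are FPKM rescaled to each library's reads in genes, given as mean ± SD. The libraries held 6660850 to 16455079 reads in genes (median 11064792). Genes with a read numbered from 6786, in VTA P30 replicate 3, to 19904. The next lowest library had 11962. Labels do not say whether libraries of a group came from separate mice. By the design the 9 libraries of an age came from 5 mice, so some share mice. The p-values measure the spread between these samples, which may be technical. Each age was sequenced in its own pool while the regions of an age shared one, so age and pool cannot be told apart. Replicates of NAc P7 lay closest together, with rank correlations of 0.914 to 0.92 across genes, against 0.494 for both pairs with VTA P30 replicate 3 and 0.589 to 0.835 for the other 22 pairs. The 27 pairs differed by more than counting error, with 18.2 to 825.7 times the variance that counting alone gives. Floors cover counting error only.

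In the libraries of the sort the dopaminergic genes Slc6a3, Th, Slc18a2, Ddc and Nr4a2 had medians of 0.156 to 2.74, while microglial genes were abundant in all 27. Of these 5 genes, Slc6a3 and Th had fewer than 3 reads in 12 of 27 libraries each, and Slc18a2, Ddc and Nr4a2 in 3, 7 and 4. Slc6a3, the gene of the dopamine transporter on which the sort was based (ENSMUSG00000021609, chromosome 13, 73536747 to 73578672 on GRCm38/mm10), had a median of 0.156 and 0 reads in 11 libraries. Its highest value was 53.4, in SNc P7 replicate 3, against 3.62 in the VTA libraries and 3.246 in those of NAc, the striatal target. In the 27 libraries 3 reads would give 0.0528 to 0.13. Th, tyrosine hydroxylase (ENSMUSG00000000214, chromosome 7, 142892752 to 142931128), had a median of 0.293 and a highest value of 26.1, with 0 reads in 12 libraries and values above 10 in 4. Pitx3, a transcription factor of midbrain dopaminergic neurons, had 0 reads in all 27 libraries, where 3 reads would give 0.119 to 0.295. Slc18a2 (vesicular monoamine transporter), Ddc (aromatic amino acid decarboxylase) and Nr4a2 (Nurr1) had medians of 1.84, 0.954 and 2.74 (77, 50 and 142 reads) and highest values of 93.4, 8.94 and 66.0. C1qa, a complement gene of microglia, was at 487 to 9316 (median 3224), P2ry12 (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871) at 36.8 to 1900, Tmem119 at 8.36 to 3730 and Cx3cr1 at 13.2 to 456. Among all genes tested, the median member of the microglia and macrophage list (16 members) lay at the 97.2 to 99.7 percentile of a library. That of the pan-neuronal list (14 members) lay at 56.6 to 94.7 and that of the dopamine list (13 members) at 32.5 to 86.2 (median 63.5). The microglia list lay above both others in 27 of 27 libraries. The astrocyte list lay at the 61.1 to 97.8 percentile.

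**Figure D1:**
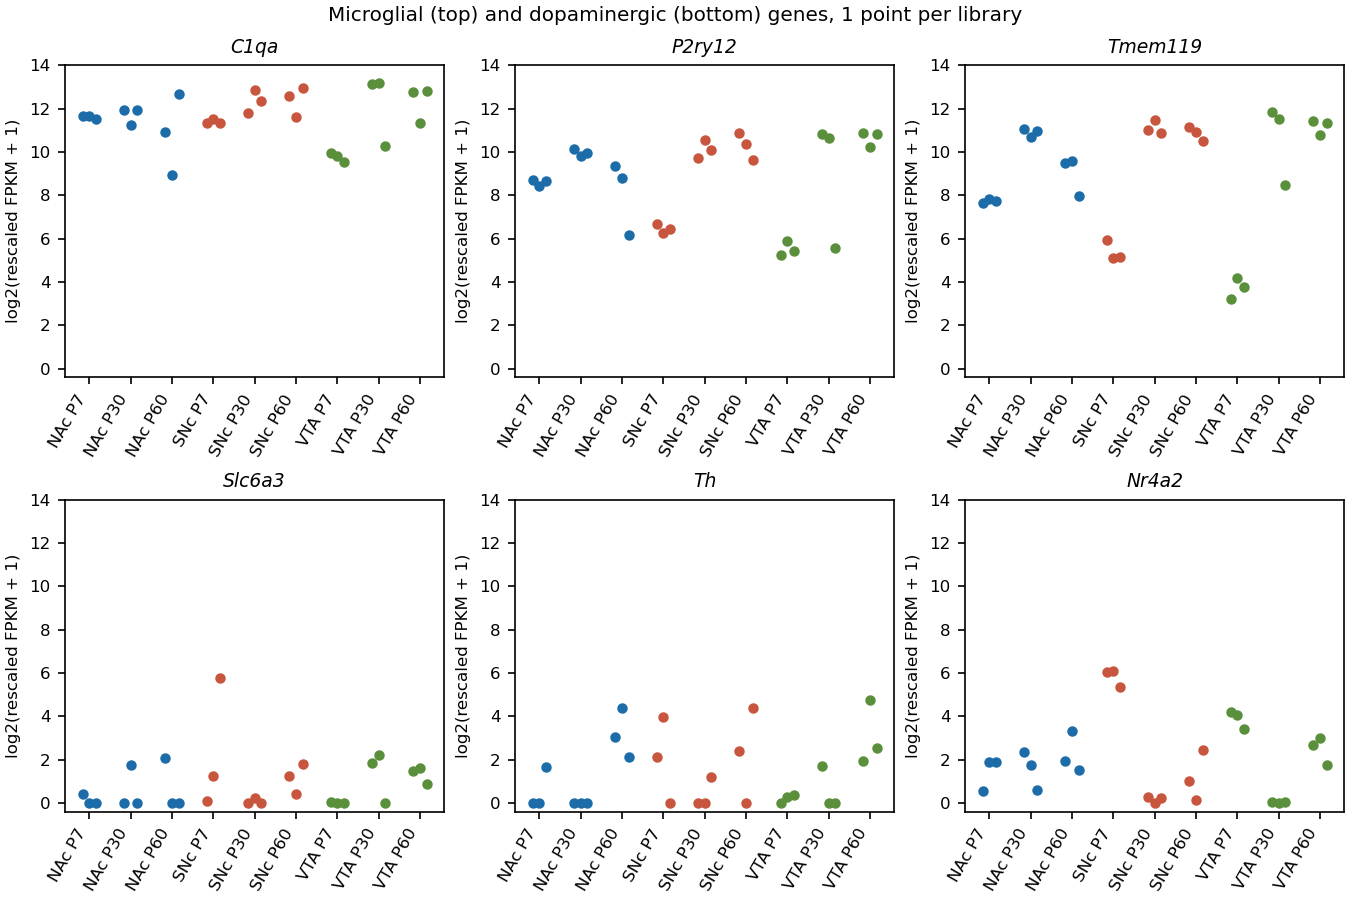
Level of C1qa, P2ry12 and Tmem119 (top) and Slc6a3, Th and Nr4a2 (bottom) as log2(rescaled FPKM + 1) on the vertical axis, with a point per library in the 9 groups on the horizontal axis (n = 3). C1qa was at 487 to 9316 in the 27 libraries, while Slc6a3 had 0 reads in 11 and Th in 12.

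The comparison of P60 with P7, averaged over the 3 regions, asked how the sorted cells changed with age. In this average myelin, astrocyte, endothelial and homeostatic microglial genes rose, and cell cycle, chemokine and axon growth genes fell. The microglial rise was not shared by the regions: the median log2 value of the homeostatic microglia list (n = 3) went from 5.07 ± 0.067 to 8.18 ± 0.84 in SNc and from 4.53 ± 0.26 to 8.38 ± 0.60 in VTA. In NAc it went from 7.56 ± 0.053 to 6.36 ± 0.44, and that of the microglia and macrophage list from 9.05 ± 0.094 to 7.71 ± 0.57. The fall of the inflammatory chemokine and cytokine list was not shared by VTA, where it was at 6.79 ± 1.38 and 6.72 ± 0.61, against 7.51 ± 0.048 and 2.31 ± 1.75 in NAc and 9.43 ± 0.23 and 6.52 ± 0.78 in SNc. Mbp, myelin basic protein (ENSMUSG00000041607, chromosome 18, 82475146 to 82585637), was at 702 ± 839.9 at P60 and 7.60 ± 6.44 at P7 (n = 9 each; log2 fold change 5.70 ± 0.30 (SE), limma adjusted p = 9.22e-12). It was above the P7 mean in 9 of 9 P60 libraries. Tmem119, a surface protein of homeostatic microglia (ENSMUSG00000054675, chromosome 5, 113793729 to 113800516), was at 1619 ± 891 and 89.1 ± 93.6 (log2 fold change 4.74 ± 0.36, adjusted p = 4.39e-09), and higher in 9 of 9. Ccl7, a chemokine that draws monocytes (ENSMUSG00000035373, chromosome 11, 82045712 to 82047525), fell from 2695 ± 3143 to 41.3 ± 33.97 (log2 fold change -5.29 ± 0.89, adjusted p = 0.000207). Nr4a2 (ENSMUSG00000026826, chromosome 2, 57106830 to 57124003) fell from 24.5 ± 26.3 to 3.78 ± 2.94 (log2 fold change -1.74 ± 0.35, adjusted p = 0.0014). It peaked in SNc P7, like immediate early genes, but in VTA P7 it was above NAc P7 and they below: its source is open. Th rose from 2.29 ± 4.77 to 9.84 ± 9.50 (log2 fold change 1.91 ± 0.55, adjusted p = 0.0202). This call was lost without SNc P7 replicate 3 or VTA P60 replicate 2 (highest adjusted p = 0.0536). The other dopaminergic genes did not pass: the log2 fold changes of Slc6a3, Slc18a2 and Ddc were 0.21 ± 0.53, -1.68 ± 0.60 and 0.86 ± 0.36 (adjusted p = 0.822, 0.0581 and 0.114). The largest increases by the rule for named genes also included Thrsp, a regulator of lipid synthesis (5.62 ± 0.36), the connexin gene Gjb6 (4.68 ± 0.40) and Selplg (4.68 ± 0.31). Others were the endothelial genes Ly6a (4.92 ± 0.75), Ly6c1 (4.60 ± 0.57) and Car4 (4.88 ± 0.64). Tpm3-rs7 (4.57 ± 0.40) shares reads with near-identical copies and is uncertain. The largest decreases included the chemokines Cxcl2 (-5.32 ± 0.73) and Ccl3 (-3.83 ± 0.59), and the microtubule-binding Crmp1 (-4.04 ± 0.30) and Dpysl3 (-3.82 ± 0.38). Further decreases were those of Marcksl1 (-4.27 ± 0.48), Tubb6 (-4.03 ± 0.60), Tlr2 (-4.15 ± 0.57), Lyve1 (-4.14 ± 0.54) and the cell cycle gene Cdca3 (-3.79 ± 0.46).

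By the fixed lists, 10 of 14 myelinating oligodendrocyte markers rose from P7 to P60 (11 adjusted over the list alone; camera adjusted p = 1.08e-15, and adjusted p = 0.000304 with an estimated correlation). Among them were Mobp (log2 fold change 4.32 ± 0.45) and Mag (2.94 ± 0.41). The astrocyte list held 10 of 14 members that rose (adjusted p = 0.00066 with an estimated correlation), such as the glutamate transporter gene Slc1a2, from 20.9 ± 15.3 to 112 ± 77.1, and Ntsr2 (4.34 ± 0.48). In the endothelial list, 10 of 13 markers rose (11 adjusted over the list alone; adjusted p = 0.00215 with an estimated correlation), such as Bsg, from 407 ± 80.1 to 1547 ± 518, and Esam (3.89 ± 0.49). Of 19 cell cycle genes, 17 fell (18 adjusted over the list alone; adjusted p = 0.00066 with an estimated correlation). The proliferation marker Mki67 went from 4.88 ± 2.45 to 0.0716 ± 0.193, and Ccnb1, cyclin B1, from 23.97 ± 25.4 to 0.234 ± 0.568. Of 17 immature neuron and axon growth genes, 14 fell (16 adjusted over the list alone; adjusted p = 0.00215 with an estimated correlation), among them Stmn2, from 64.9 ± 48.9 to 8.02 ± 9.56. Of 16 microglia and macrophage markers, 7 rose, such as Ctss (1.78 ± 0.26) and P2ry12 (2.82 ± 0.52), and 2 fell, among them Fcrls (-3.10 ± 0.59) (adjusted p = 3.1e-06, and adjusted p = 0.193 with an estimated correlation). The dopamine list held 5 genes that rose and 1 that fell (adjusted p = 0.00648, and adjusted p = 0.101 with an estimated correlation; 7 and 2 adjusted over the list alone). Besides Th, these included Aldh1a1 (retinaldehyde dehydrogenase; 3.20 ± 0.47), which other cell types also express. Gch1, which makes the cofactor of tyrosine hydroxylase, fell (-1.63 ± 0.28).

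Other lists called from P7 to P60 did not hold with an estimated correlation. Of 9 blood cell markers, 5 fell, with the hemoglobin genes Hba-a1 (-3.26 ± 0.56) and Hbb-bs (-2.66 ± 0.52), which share reads with near-identical copies (adjusted p = 0.0108, and adjusted p = 0.287 with an estimated correlation). The adjusted p was 0.0667 without 4 libraries (VTA P30 replicate 3, NAc P60 replicate 3, SNc P60 replicate 3 and VTA P60 replicate 2). In NAc the blood list went from 2.43 at P7 to 3.27 at P60 (median log2 value, n = 3) and the ion channel list from 1.12 to 1.86, and in VTA the mural list went from 1.91 to 1.63 and the precursor list from 2.53 to 1.94. Of 23 axon guidance genes 8 fell, such as Nrp2 (-2.20 ± 0.33; adjusted p = 0.144 with an estimated correlation). Of 19 cholesterol synthesis genes 6 fell (9 adjusted over the list alone), such as Hmgcs1 (-1.52 ± 0.31), and 1 rose (adjusted p = 0.287 with an estimated correlation). Of 76 cytosolic ribosomal protein genes, which have many pseudogene copies, 7 fell (3 adjusted over the list alone), such as Rps25 (-1.41 ± 0.32; adjusted p = 0.488 with an estimated correlation). Of 27 voltage-gated ion channel genes 5 fell (9 adjusted over the list alone), such as Cacna1b (-2.24 ± 0.29), and Kcna2 rose (1.27 ± 0.26; adjusted p = 0.445 with an estimated correlation, and 0.0788 without the 4 libraries). Of 10 mural and fibroblast markers 3 rose (adjusted p = 0.144 with an estimated correlation). Of 7 ependymal and choroid plexus markers 2 rose (adjusted p = 0.151 with an estimated correlation). Of 10 oligodendrocyte precursor markers 3 rose (4 adjusted over the list alone), such as Bcas1 (2.26 ± 0.38), and 1 fell (adjusted p = 0.287 with an estimated correlation, and 0.101 without the 4 libraries).

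The remaining 17 lists were not called between P60 and P7, but without the 4 libraries nuclear oxidative phosphorylation genes were called higher (adjusted p = 0.00675), and sex-linked (adjusted p = 0.0331) and proteasome genes (adjusted p = 0.0456) lower. Among synaptic and neuronal lists these were GABA and glycine receptors (6 fell of 17, adjusted p = 0.109), glutamate receptors and postsynaptic scaffolds (2 rose and 7 fell of 28, adjusted p = 0.109) and synaptic vesicle and release genes (5 fell of 21, adjusted p = 0.109). So were GABAergic neuron markers (1 rose and 1 fell of 13, adjusted p = 0.454), glutamatergic neuron markers (3 rose and 1 fell of 8, adjusted p = 0.0711) and pan-neuronal genes (4 fell of 14, adjusted p = 0.455). The lists of neuropeptides (4 fell of 14, adjusted p = 0.295) and striatal projection neuron markers (1 rose and 2 fell of 19, adjusted p = 0.771) completed these. Syp fell by 1.32 and Glra2 by 2.50 on the log2 scale. Among dopaminergic lists they were midbrain dopaminergic transcription factors (1 rose and 1 fell of 4, adjusted p = 0.475), SNc-enriched dopaminergic genes (3 rose and 2 fell of 11, adjusted p = 0.386) and VTA-enriched dopaminergic genes (2 fell of 11, adjusted p = 0.811). The SNc-enriched members that moved are not specific to dopaminergic neurons: Aldh1a1 and Sox6, a transcription factor also of the oligodendrocyte lineage (1.06 ± 0.30), rose, and Igf1, a growth factor that microglia of young brains make (-2.71 ± 0.44), fell. Lpl, lipoprotein lipase, fell in the VTA-enriched list (-2.90 ± 0.39). Among lists of general function and sex they were immediate early and dissociation stress genes (3 rose and 6 fell of 23, adjusted p = 0.893), mitochondrially encoded genes (2 rose and 2 fell of 13, adjusted p = 0.268) and nuclear oxidative phosphorylation genes (0 passed of 52, adjusted p = 0.137). So were Parkinson disease genes (3 fell of 14, adjusted p = 0.165), proteasome genes (4 fell of 31, adjusted p = 0.137) and sex-linked genes (1 fell of 4, adjusted p = 0.109). The immediate early list had a median log2 fold change of -0.078, while its test pointed upward. Egr2, an immediate early gene, fell (-3.08 ± 0.70), and Hspa1a rose (2.62 ± 0.51). The list of cholinergic, serotonergic and noradrenergic markers had no member above the filter on low values.

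Of 18888 genes tested with limma, 2883 differed between P60 and P7, 889 higher and 1994 lower (30.8% higher). This split depended on the scaling, with 44.1% higher after quantile normalization, 42.7% on the deposited scale and 45.1% without the 4 libraries. The median of all genes was -0.16 (log2), to which these changes are relative.

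**Figure D2:**
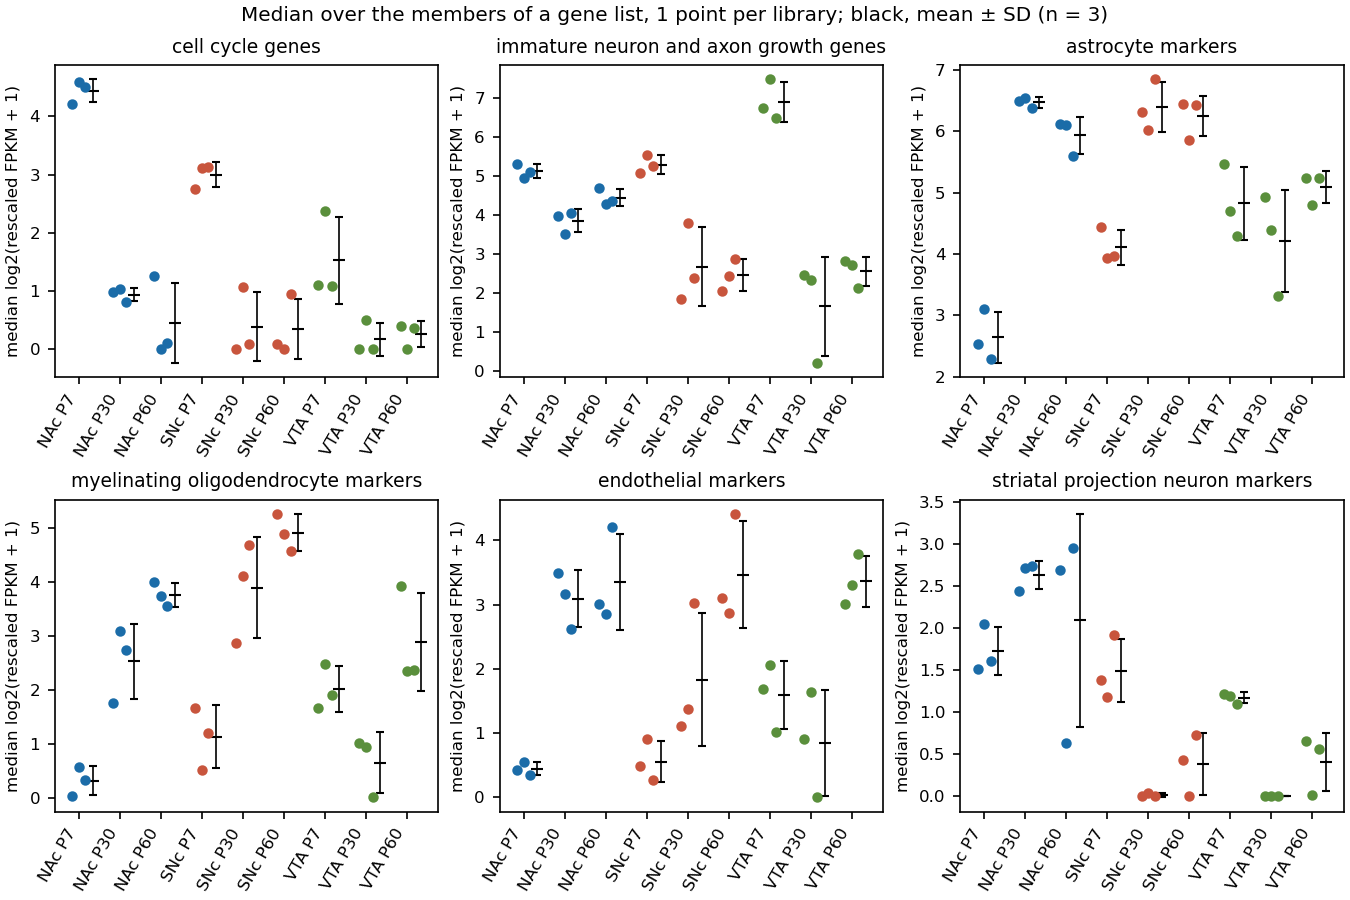
Median log2(rescaled FPKM + 1) over the members of 6 gene lists per library (points) on the vertical axis, with the mean ± SD (n = 3) of the 9 groups on the horizontal axis. The cell cycle list was at 4.44 in NAc P7 and 0.450 in NAc P60.

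The comparison of P30 with P7 asked which of these differences were present at the intermediate age. Averaged over the regions, homeostatic microglial and astrocyte genes rose and cell cycle and axon growth genes fell. Of 11 inflammatory chemokine and cytokine genes, a list added after levels were seen, 8 fell (10 adjusted over the list alone; adjusted p = 4.99e-06, and adjusted p = 0.0961 with an estimated correlation). The astrocyte list did not have higher values in VTA: its median log2 value (n = 3) there was 4.82 ± 0.60 at P7 and 4.21 ± 0.83 at P30, against 2.64 ± 0.42 and 6.47 ± 0.086 in NAc. In VTA the myelin list went from 2.02 ± 0.42 to 0.65 ± 0.56 and the endothelial list from 1.59 ± 0.53 to 0.85 ± 0.82. These differences between regions were not tested for these ages alone. VTA P30 replicate 3 was the lowest VTA P30 library in the astrocyte, myelin and endothelial lists, at 3.31, 0.008 and 0. Replicates 1 and 2 were at 4.937 and 4.392, 1.013 and 0.94, and 0.904 and 1.646. Tmem119 rose from 89.1 ± 93.6 to 2176 ± 944 (n = 9 each; log2 fold change 5.26 ± 0.36, adjusted p = 6.75e-10). Thrsp rose by 5.92 ± 0.36, Selplg, the ligand of P-selectin, by 5.35 ± 0.31, and Gjb6 by 5.30 ± 0.40. H2-Ab1 and H2-Aa, the class II antigen presentation genes, rose by 4.67 ± 0.91 and 4.61 ± 0.82. Ccl7 fell from 2695 ± 3143 to 61.8 ± 76.1 (log2 fold change -5.16 ± 0.89, adjusted p = 0.000175) and Cxcl2 by 4.67 on the log2 scale. Stmn2, stathmin 2 of growing axons, fell from 64.9 ± 48.9 to 2.96 ± 2.94 (-4.14 ± 0.35). Nr4a2 fell from 24.5 ± 26.3 to 0.825 ± 1.45 (log2 fold change -3.13 ± 0.35, adjusted p = 1.23e-06), while Slc6a3 (-0.17 ± 0.53), Th (-0.61 ± 0.55), Slc18a2 (-1.41 ± 0.60) and Ddc (-0.44 ± 0.36) did not pass. Rn7sk (4.92 ± 0.30) and the mitochondrial tRNA genes mt-Te (-4.75 ± 0.65) and mt-Tl1 (-4.43 ± 0.68) are short or copied genes whose values are uncertain. Mir1195 had 0 reads in the 9 P30 libraries and a mean of 42.04 ± 28.9 at P7.

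Of 14 astrocyte markers 10 rose from P7 to P30 (adjusted p = 0.00316 with an estimated correlation), with Slc4a4 at 2.44 ± 0.27. Of 14 myelin markers 7 rose (8 adjusted over the list alone; adjusted p = 0.00959 with an estimated correlation), with Mag at 2.98 ± 0.41 and Mbp at 3.50 ± 0.30. Of 7 ependymal and choroid plexus markers 3 rose (adjusted p = 0.0405 with an estimated correlation). Of 16 microglia and macrophage markers 11 rose, such as Ctss, a lysosomal protease (1.89 ± 0.26), Aif1 (1.93 ± 0.30) and C1qb (1.43 ± 0.23), and 2 fell (12 and 3 adjusted over the list alone). The list had a camera adjusted p = 4.58e-09, and an adjusted p = 0.0734 with an estimated correlation. Of 13 endothelial markers 6 rose (adjusted p = 0.0708 with an estimated correlation). Of 19 cell cycle genes 17 fell (18 adjusted over the list alone; adjusted p = 0.00614 with an estimated correlation), with Birc5 at -2.62 ± 0.32. Of 17 immature neuron and axon growth genes 13 fell (14 adjusted over the list alone; adjusted p = 0.00721 with an estimated correlation). Of 21 synaptic vesicle and release genes 16 fell, such as Syn1 (-3.00 ± 0.38) and Syt1 (-2.63 ± 0.36), and 1 rose (adjusted p = 0.0405 with an estimated correlation). Of 13 GABAergic neuron markers 8 fell (adjusted p = 0.0405 with an estimated correlation), such as Gad1 (-1.76 ± 0.38). Of 14 pan-neuronal genes 9 fell (10 adjusted over the list alone) (adjusted p = 3.56e-05, and adjusted p = 0.108 with an estimated correlation). In NAc the synaptic vesicle list went from 3.55 ± 0.015 to 3.80 ± 0.29 (median log2 value, n = 3) and the pan-neuronal list from 3.10 ± 0.14 to 3.76 ± 0.26. The synaptic vesicle list went from 3.75 ± 0.26 to 1.29 ± 0.52 in SNc and from 4.97 ± 0.31 to 0.86 ± 0.72 in VTA. The microglia and macrophage list was at 9.05 ± 0.094 and 9.03 ± 0.22 in NAc. Camera called 20 of 32 lists, 7 higher and 13 lower, of which 3 and 4 held with an estimated correlation. In total 4464 genes differed, 1120 higher and 3344 lower, around a median of all genes of -0.26. The share of higher genes was 25.1%, against 42.7% after quantile normalization and 37.8% without the 4 libraries.

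From P30 to P60, averaged over the regions, neuronal and myelin genes rose. Cck (cholecystokinin) went from 1.48 ± 2.81 to 40.2 ± 55.8 (n = 9 each; log2 fold change 3.39 ± 0.49, adjusted p = 0.000663). Avp (vasopressin) went from 1.74 ± 3.84 to 42.99 ± 56.3 (3.55 ± 0.61). Mobp, a myelin protein, went from 5.95 ± 7.22 to 73.1 ± 75.1 (log2 fold change 3.18 ± 0.45, adjusted p = 0.000532) and Nrgn, neurogranin, from 3.20 ± 3.20 to 43.8 ± 58.7 (2.79 ± 0.36). Pvalb, parvalbumin, rose by 2.50 ± 0.43 and Th by 2.52 ± 0.55 (adjusted p = 0.0218, and 0.0925 when only the compared libraries were fitted). Slc6a3 (0.39 ± 0.53), Slc18a2 (-0.27 ± 0.60), Ddc (1.29 ± 0.36) and Nr4a2 (1.39 ± 0.35) did not pass. CT010467.1, which holds 18S rRNA, fell from 2424 ± 1454 to 206 ± 149.9 (log2 fold change -3.69 ± 0.63, adjusted p = 0.00346). It took 0.0057 to 0.0085% of the reads in NAc P60 replicate 3, SNc P60 replicate 3 and VTA P60 replicate 2. Rn7sk fell by 2.08 on the log2 scale. Of 14 myelin markers 5 rose (adjusted p = 0.0236 with an estimated correlation), among them Opalin (2.37 ± 0.46; adjusted p = 0.0837 when only the compared libraries were fitted) and Mbp (2.19 ± 0.30; adjusted p = 0.105 on the deposited scale).

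Of 21 synaptic vesicle and release genes 2 rose over all genes tested and 13 adjusted over the list alone (adjusted p = 0.0236 with an estimated correlation). Of 14 pan-neuronal genes 2 rose (9 adjusted over the list alone; adjusted p = 0.0332 with an estimated correlation), with Nefl, a neurofilament gene, at 1.93 ± 0.36. Of 13 endothelial markers 2 rose (8 adjusted over the list alone; adjusted p = 0.0306 with an estimated correlation), with Slco1a4 at 2.05 ± 0.38. The glutamatergic list had 2 of 8 members that rose (3 adjusted over the list alone), such as Neurod2 (1.87 ± 0.35; adjusted p = 0.0306 with an estimated correlation, and 0.0789 without the 4 libraries). Of 13 GABAergic markers 1 rose, Pvalb (5 adjusted over the list alone; adjusted p = 0.0236 with an estimated correlation). Of 11 VTA-enriched genes 1 rose, Cck, a neuropeptide of many neurons (3 adjusted over the list alone; adjusted p = 0.0332 with an estimated correlation). Beside these, the mitochondrially encoded list was called higher (1 of 13 rose, 6 adjusted over the list alone; adjusted p = 0.000487, and adjusted p = 0.267 with an estimated correlation), with a median log2 value of 8.31 in NAc P30 and 10.25 in NAc P60 but 9.15 and 8.73 in VTA. So was the immediate early and dissociation stress list (0 of 23 passed, 2 adjusted over the list alone; adjusted p = 0.00404, adjusted p = 0.425 with an estimated correlation, and 0.0502 without the 4 libraries). The microglia and macrophage list was called lower (0 of 16 passed, 1 adjusted over the list alone; adjusted p = 0.00217, and adjusted p = 0.425 with an estimated correlation), at 9.03 in NAc P30 and 7.71 in NAc P60 but 9.23 and 9.26 in SNc and 9.45 and 9.34 in VTA. Camera called 15 of 32 lists, 12 higher and 3 lower, of which 7 and 0 held with an estimated correlation. In total 211 genes differed, 176 higher and 35 lower (83.4% higher, against 58.2% without VTA P30 replicate 3, 70.0% after quantile normalization and 72.1% without the 4 libraries). Of 32 calls of genes chosen by the rule, 22 were kept in all fits without a library and 6 under all alternatives. The count was 320 without NAc P60 replicate 4, 364 without VTA P30 replicate 3, 139 without VTA P60 replicate 1, 599 without the 4 libraries and 56 when only the compared libraries were fitted.

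**Figure D3:**
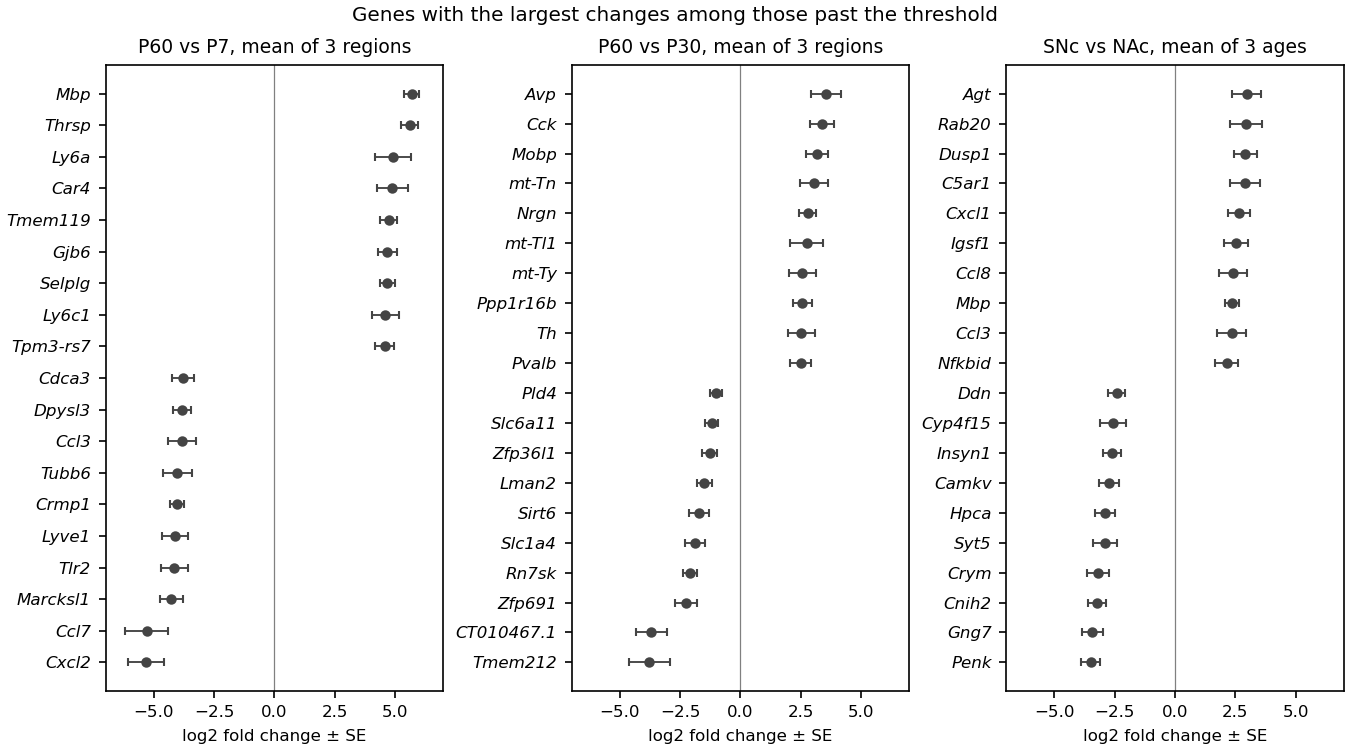
Log2 fold change (horizontal axis) of the genes with the largest changes by the rule for named genes in P60 vs P7, P60 vs P30 and SNc vs NAc, as points with bars for the SE. Mbp had the largest increase of those drawn from P7 to P60, at 5.70.

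The regional comparisons asked how the sorted cells differ between midbrain cell groups and their striatal target. SNc libraries, averaged over the ages, had lower levels of genes of striatal neurons than NAc libraries and higher levels of immediate early and dissociation stress genes. Penk, preproenkephalin (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819), was at 10.8 ± 9.11 in SNc and 88.4 ± 49.3 in NAc (n = 9 each; log2 fold change -3.50 ± 0.40, adjusted p = 7.72e-05). Of 9 SNc libraries, 9 lay below the NAc mean. Gng7, a G protein subunit of striatal neurons (-3.42 ± 0.45), Cnih2 (-3.24 ± 0.38), Crym (-3.20 ± 0.45) and Hpca, hippocalcin (-2.90 ± 0.41), were lower too. Dusp1, an early response phosphatase, was at 2223 ± 1167 against 392 ± 288 (log2 fold change 2.92 ± 0.46, adjusted p = 0.00129). Agt, angiotensinogen of astrocytes, was at 367 ± 257 against 107 ± 109 (2.97 ± 0.60) and Mbp at 669 ± 869 against 80.2 ± 94.7 (2.36 ± 0.30). The chemokine Cxcl1 (2.64 ± 0.46) and the complement receptor C5ar1 (2.92 ± 0.62) were higher, calls lost with a pseudocount of 0.1 (adjusted p = 0.0658 and 0.0534). Slc6a3 (0.73 ± 0.53), Th (0.32 ± 0.55), Slc18a2 (-0.11 ± 0.60), Ddc (0.33 ± 0.36) and Nr4a2 (0.64 ± 0.35) did not pass.

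Of 19 striatal projection neuron markers 9 were lower in SNc than in NAc (15 adjusted over the list alone; adjusted p = 1.48e-05 with an estimated correlation), such as the transcription factor Bcl11b (-2.29 ± 0.28) and the phosphodiesterase Pde10a (-1.74 ± 0.30). Lower were also 7 of 21 synaptic vesicle genes (15 adjusted over the list alone; adjusted p = 0.00344 with an estimated correlation), such as Syt1 (-2.07 ± 0.36). Of 28 glutamate receptor and scaffold genes 6 were lower (14 adjusted over the list alone; adjusted p = 0.0162 with an estimated correlation), with Camk2a at -2.37 ± 0.38. Of 14 pan-neuronal genes 5 were lower (9 adjusted over the list alone; adjusted p = 0.0454 with an estimated correlation), and of 27 ion channel genes 4 (10 adjusted over the list alone; adjusted p = 0.0355 with an estimated correlation). Of 13 GABAergic markers 1 was lower, Dlx6 (6 adjusted over the list alone; adjusted p = 0.0181 with an estimated correlation). Of 14 neuropeptides 1 was lower, Penk (5 adjusted over the list alone; adjusted p = 0.0407 with an estimated correlation). Of 23 immediate early and dissociation stress genes 3 were higher (14 adjusted over the list alone; adjusted p = 0.0124 with an estimated correlation), namely Dusp1, Ier2 (1.49 ± 0.35) and Jun (1.81 ± 0.44). The calls of Ier2 and Jun were each lost in over 10 of 27 fits without a library (highest adjusted p = 0.0694 and 0.0739). Of 14 myelin markers Mbp was higher (5 adjusted over the list alone; adjusted p = 0.00146 with an estimated correlation). At P7 alone, 5 of these neuronal lists had higher values in SNc. The median log2 value in SNc P7 and NAc P7 was 3.75 against 3.55 for synaptic vesicle, 1.86 against 1.29 for glutamate receptor, 3.58 against 3.10 for pan-neuronal, 1.60 against 1.12 for ion channel and 2.82 against 1.90 for neuropeptide genes (n = 3). At P30 and P60 the synaptic vesicle list was at 1.29 against 3.80 and 2.10 against 5.11. Camera called 19 of 32 lists, 7 higher and 12 lower, of which 2 and 7 held with an estimated correlation. In total 255 genes differed, 43 higher and 212 lower, around a median of all genes of -0.16. The share of higher genes was 16.9%, against 47.7% after quantile normalization, 27.4% without VTA P30 replicate 3, 31.6% when only the compared libraries were fitted and 30.1% without the 4 libraries. The count was 140, 121 and 140 without NAc P7 replicates 1, 2 and 3 and 136 and 166 without SNc P7 replicates 1 and 3. It was 153 without SNc P60 replicate 3, 438 without VTA P30 replicate 3, 575 without the 4 libraries, 548 when only the compared libraries were fitted and 108 with a pseudocount of 0.1.

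VTA libraries, averaged over the ages, had lower levels of striatal neuron and cell cycle genes than NAc libraries. Penk was at 5.11 ± 6.30 in VTA and 88.4 ± 49.3 in NAc (n = 9 each; log2 fold change -4.49 ± 0.40, adjusted p = 8.52e-07). Ppp1r1b, the gene of DARPP-32 in striatal projection neurons, was at 7.96 ± 8.06 against 73.5 ± 28.8 (-3.89 ± 0.50). Crym (-4.00 ± 0.45), Gng7 (-3.67 ± 0.45) and Camk2a (-2.87 ± 0.38) were lower too. Klf2, a transcription factor, was higher (1.86 ± 0.41; adjusted p = 0.0149). This call was lost under 4 of 9 alternatives, among them the deposited scale (range 0.00548 to 0.0892 with the fits without a library). Slc6a3 (0.43 ± 0.53), Th (0.043 ± 0.55), Slc18a2 (0.86 ± 0.60), Ddc (-0.38 ± 0.36) and Nr4a2 (0.37 ± 0.35) did not pass. Of 19 striatal projection neuron markers 10 were lower (15 adjusted over the list alone; adjusted p = 3.18e-05 with an estimated correlation). Of 19 cell cycle genes 5 were lower (14 adjusted over the list alone; adjusted p = 0.0393 with an estimated correlation), with Ccnb1 at -2.13 ± 0.25. Of 28 glutamate receptor and scaffold genes 6 were lower (14 adjusted over the list alone; adjusted p = 3.08e-06, and adjusted p = 0.0893 with an estimated correlation). Of 21 synaptic vesicle genes 6 were lower (11 adjusted over the list alone; adjusted p = 1.74e-05, and adjusted p = 0.0804 with an estimated correlation). Of 23 immediate early and dissociation stress genes 2 were higher (5 adjusted over the list alone), Dusp1 (2.09 ± 0.46) among them, and Arc was lower (-2.23 ± 0.44; adjusted p = 0.0804 with an estimated correlation). At P7 the last 3 of these lists stood the other way: the synaptic vesicle list was at 4.97 against 3.55 in NAc (median log2 value, n = 3), the glutamate receptor list at 2.94 against 1.29 and the immediate early list at 6.95 against 7.77. The synaptic vesicle list was at 0.86 against 3.80 at P30 and 2.37 against 5.11 at P60, and the glutamate receptor list at 0.55 against 2.21 and 0.84 against 2.64. Camera called 10 of 32 lists, 3 higher and 7 lower, of which 0 and 2 held with an estimated correlation. In total 368 genes differed, 13 higher and 355 lower, around a median of all genes of -0.29. The share of higher genes was 3.5%, against 22.3% after quantile normalization, 13.9% without VTA P30 replicate 3, 11% without VTA P7 replicate 3 and 18.2% without the 4 libraries. The count was 211, 206 and 208 without NAc P7 replicates 1, 2 and 3, 569 without NAc P60 replicate 3, 148 after quantile normalization and 192 on the deposited scale.

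Averaged over the ages, fewer genes were called between VTA and SNc, the midbrain regions, than between either and NAc, and myelin genes were lower in VTA. At P7 alone the count was 394, against 96 between SNc and NAc. The calls were 13 genes, 0 higher and 13 lower in VTA, averaged over the ages, beside 1659 at an unadjusted p under the threshold. Mbp was at 64.2 ± 48.01 in VTA and 669 ± 869 in SNc (n = 9 each; log2 fold change -1.67 ± 0.30, adjusted p = 0.0225). The chemokine Ccl8 was at 1.31 ± 2.55 and 22.1 ± 20.8 (-3.06 ± 0.58, adjusted p = 0.0318) and Ccnb1 at 0.0355 ± 0.106 and 5.61 ± 9.63 (-1.40 ± 0.25, adjusted p = 0.0225). These calls were lost in 7, 14 and 5 of the 27 fits without a library, with a highest adjusted p of 0.0733, 0.0921 and 0.0618, so 0 of 3 were kept in all of them. Of 14 myelin markers 1 was lower over all genes tested, Mbp, and 8 adjusted over the list alone (adjusted p = 0.023 with an estimated correlation). Of 14 astrocyte markers 0 passed and 3 were lower adjusted over the list alone (adjusted p = 0.000264, and adjusted p = 0.146 with an estimated correlation). Camera called 6 of 32 lists higher in VTA and 7 lower, of which 0 and 1 held with an estimated correlation. Among those called higher, with 0 members that passed, were voltage-gated ion channels (adjusted p = 6.29e-06, and adjusted p = 0.146 with an estimated correlation), mitochondrially encoded genes (adjusted p = 5.64e-05, and 0.255) and synaptic vesicle genes (adjusted p = 0.00173, and 0.255). At P7 the myelin list was at 2.02 ± 0.42 in VTA and 1.13 ± 0.58 in SNc (median log2 value, n = 3), and the astrocyte list at 4.82 ± 0.60 and 4.11 ± 0.28. At P60 the myelin list was at 2.88 ± 0.90 and 4.91 ± 0.34. The log2 fold changes of Slc6a3, Th, Slc18a2, Ddc and Nr4a2 were -0.30 ± 0.53, -0.28 ± 0.55, 0.97 ± 0.60, -0.71 ± 0.36 and -0.28 ± 0.35, and 0 of the 5 passed. The count of genes was 5 and 0 without SNc P60 replicates 1 and 4, and 26, 33 and 23 without VTA P7 replicates 1, 2 and 3, of which 8, 8 and 6 were higher. Without NAc P30 replicate 1, NAc P60 replicate 3 or SNc P7 replicate 1, a single gene was higher. The count was 5 without VTA P60 replicate 3, 10 without VTA P60 replicate 2 (2 higher), 8 without the 4 libraries (2 higher), 69 with voom (19 higher) and 0 among genes with a mean of at least 5.

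The effect of age differed between the regions for 2259 genes (region by age interaction, 4 degrees of freedom). Ttr, transthyretin of the choroid plexus, was at 975 ± 1060 in NAc P60, 3025 ± 4132 in SNc P30 and 259 ± 222 in VTA P7 (n = 3 each; adjusted p = 8.35e-05). It was at most 53.4 ± 31.7 in the other 6 groups. Ccnb1 was at 55.3 ± 8.28 in NAc P7 and 16.5 ± 10.3 in SNc P7, against 0.106 ± 0.184 in VTA P7 (adjusted p = 0.00011). Dclk1, doublecortin-like kinase, went from 4.81 ± 1.00 at P7 to 24.7 ± 10.2 at P60 in NAc and from 22.2 ± 3.40 to 5.90 ± 1.85 in VTA (adjusted p = 0.000262). Snhg11, Myt1l, Nrxn3, Gnao1 and Clip3 were among the 10 genes with the smallest p. Nr4a2 went from 57.3 ± 14.8 to 1.86 ± 2.32 in SNc, but from 1.98 ± 1.33 to 4.59 ± 3.95 in NAc (adjusted p of this difference 0.00367). The P60 vs P7 change differed for 2503 genes between VTA and NAc, 174 between SNc and NAc and 73 between VTA and SNc. Of 14 pan-neuronal genes 12 had a lower change in VTA than in NAc and 0 a higher one (median difference -4.04; adjusted p = 0.0132 with an estimated correlation). Of 16 microglia and macrophage markers 11 had a higher change and 0 a lower one (median difference 3.54; adjusted p = 0.0245 with an estimated correlation). The count of the interaction was 1308, 1423 and 1349 without NAc P7 replicates 1, 2 and 3, and 3758 without the 4 libraries.

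Within NAc, 1811 genes (1097 higher, 714 lower) differed between P30 and P7, 1953 genes (831 higher, 1122 lower) between P60 and P7 and 497 genes (170 higher, 327 lower) between P60 and P30 (n = 3 each). Agt rose to P30 from 0.875 ± 0.813 to 245 ± 26.2 (7.14 ± 1.05), Gjb6 by 6.52 ± 0.69, and Ccnb1 fell from 55.3 ± 8.28 to 0.0452 ± 0.0783 (-5.74 ± 0.44). Dmrtb1 had 0 reads in the 3 P30 libraries and 47.8 ± 4.10 at P7. By P60 Ntsr2, an astrocyte receptor, rose by 6.31 ± 0.84 and Ttr by 6.53 ± 1.06, while Ccl3 fell from 1990 ± 308 to 56.4 ± 62.2 (-6.72 ± 1.03) and Tnf from 327 ± 47.2 to 4.72 ± 4.12 (-6.26 ± 1.23). From P30 to P60 Ttr rose by 7.55 ± 1.06 and the uncertain mt-Tn by 6.18 ± 0.99. Tmem212, an ependymal gene at 67.8 ± 16.02 in P30, and Mir5616, at 55.3 ± 57.7, had 0 reads in the 3 P60 libraries. Mitochondrial genes took 18.5 to 22.8% of the reads in NAc P60, against 6.05 to 8.14% in NAc P30 and 6.03 to 8% in NAc P7. Of the P60 vs P30 genes 34.2% were higher, against 54.3% on the deposited scale and 54.5% without NAc P60 replicate 3. Of the P60 vs P7 genes 42.5% were higher, against 55.4% on the deposited scale, 53.2% with voom and 52.3% and 50.1% without NAc P60 replicates 3 and 4. The P30 vs P7 count was 864, 921 and 824 without NAc P7 replicates 1, 2 and 3 and 1150 without NAc P30 replicate 2. The P60 vs P7 count was 956, 1042 and 936 without the same P7 libraries, and the P60 vs P30 count 288 without NAc P60 replicate 3.

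Within SNc, 1249 genes (289 higher, 960 lower) differed between P30 and P7, 720 genes (201 higher, 519 lower) between P60 and P7 and 14 genes (9 higher, 5 lower) between P60 and P30 (n = 3 each). Mbp rose from 7.31 ± 2.27 at P7 to 1785 ± 422 at P60 (log2 fold change 7.76 ± 0.52, adjusted p = 2.04e-09) and Mobp by 6.69 ± 0.78. The chemokines Cxcl2 (-7.61 ± 1.26) and Ccl24 (-7.20 ± 0.99) fell by P60, and Ccl7, from 6743 ± 223 to 64.8 ± 95.1 (-8.76 ± 1.53), and Ccl2, from 8103 ± 384 to 101 ± 67.2 (-6.51 ± 1.32), by P30. H2-Ab1 (7.08 ± 1.57) and H2-Aa (6.92 ± 1.42) rose by P30. From P30 to P60 Trac, the T cell receptor alpha constant gene, rose by 4.21 ± 0.64, and Bcas1, of newly formed oligodendrocytes, by 4.09 ± 0.66, while the small nucleolar RNA Snord118 fell by 4.08 on the log2 scale. The P30 vs P7 count was 703, 687 and 687 without SNc P7 replicates 1, 2 and 3 and 682 and 688 without SNc P30 replicates 1 and 3. The P60 vs P7 count was 455, 412 and 439 without the same P7 libraries and 413 and 479 without SNc P60 replicates 3 and 4. The P60 vs P30 count was 8, 23 and 9 without SNc P30 replicates 1, 2 and 3, of which 2, 7 and 4 were higher.

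Within VTA, 3583 genes (393 higher, 3190 lower) differed between P30 and P7, 1885 genes (678 higher, 1207 lower) between P60 and P7 and 12 genes (12 higher, 0 lower) between P60 and P30 (n = 3 each). Tmem119 rose from 12.7 ± 4.27 at P7 to 2348 ± 1768 at P30 (6.90 ± 0.62) and 2385 ± 528 at P60 (7.47 ± 0.62), and Selplg by 6.90 ± 0.53 to P30. Bin2 had 0 reads in the 3 P7 libraries and 202 ± 44.9 at P60. The neuronal noncoding RNA Snhg11 fell from 149 ± 33.1 to 0.357 ± 0.265 by P30 (-6.79 ± 0.62) and Ttr by 6.60 on the log2 scale. Fabp7, a lipid carrier of radial glia, fell from 356 ± 66.7 to 2.37 ± 1.68 by P60 (-6.88 ± 0.67). Hba-a2, which shares reads with Hba-a1, fell by 6.79. From P30 to P60 Tinagl1 (3.94 ± 0.51) and Itm2a (4.68 ± 0.91) rose. Mitochondrial genes took 13.25 to 21.7% of the reads in VTA P7, 9.89 to 19.9% in VTA P30 and 9.78 to 11.3% in VTA P60. Of the P30 vs P7 genes 11% were higher, against 30.6% on the deposited scale and 32.7% without VTA P30 replicate 3. The 12 P60 vs P30 genes were all higher, but without VTA P30 replicate 3 the count was 13, with 6 higher and 7 lower, and on the deposited scale 70.0% were higher. Of the P60 vs P7 genes 36.0% were higher, against 50.6% with a pseudocount of 0.1. The P60 vs P7 count was 1185 without VTA P60 replicate 2, and the P60 vs P30 count 130 and 60 without VTA P30 replicates 1 and 2.

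Between regions at P7, 96 genes (70 higher, 26 lower) differed between SNc and NAc, 1091 genes (638 higher, 453 lower) between VTA and NAc and 394 genes (126 higher, 268 lower) between VTA and SNc (n = 3 each). Cxcl1 was at 183 ± 59.2 in SNc and 1.70 ± 0.847 in NAc (6.08 ± 0.80) and Avp at 382 ± 572 and 1.23 ± 0.737 (6.06 ± 1.05). Arl11 (-3.30 ± 0.73) and the immunoglobulin segment Ighj4 (-3.15 ± 0.66) were lower in SNc, with calls lost in 6 and 5 of the 6 fits without a library. In VTA Agt (7.03 ± 1.05) and Ttr (4.89 ± 1.06) were higher than in NAc, and Ppp1r1b (-5.98 ± 0.87) and Ccnb1, at 0.106 ± 0.184 against 55.3 ± 8.28, were lower. Against SNc, the macrophage gene Cd209f (-6.36 ± 1.36) and Casp1, the caspase of the inflammasome (-5.17 ± 1.02), were lower in VTA. The antisense transcript Lrp8os2, which an unstranded library cannot tell from Lrp8, was higher (3.14 ± 0.67). The 5S rRNA gene n-R5s200 was at 29.4 ± 30.3 with 0 reads in the 3 SNc libraries. The SNc vs NAc count was 54, 43 and 53 without NAc P7 replicates 1, 2 and 3 and 61 without SNc P7 replicate 3, and on the deposited scale 84.0% of its genes were higher, against 72.9%. The share of higher genes in VTA vs NAc was 58.5%, against 33.2% with a pseudocount of 0.1 and 47.7% without NAc P7 replicate 1. In VTA vs SNc it was 32.0%, against 54.2% without VTA P7 replicate 3, 20.6% and 18.9% without SNc P7 replicates 1 and 3, and 6.9% with a pseudocount of 0.1. The VTA vs NAc count was 390, 475 and 428 without the same NAc libraries, and the VTA vs SNc count 170, 186 and 175 without SNc P7 replicates 1, 2 and 3.

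At P30, 429 genes (40 higher, 389 lower) differed between SNc and NAc, 2629 genes (95 higher, 2534 lower) between VTA and NAc and 51 genes (0 higher, 51 lower) between VTA and SNc (n = 3 each). Penk was at 0.596 ± 1.03 in SNc, 0.0884 ± 0.0780 in VTA and 71.4 ± 14.7 in NAc (log2 fold changes -5.66 ± 0.69 and -6.04 ± 0.69). Dusp1 was higher than in NAc in SNc (5.32 ± 0.80) and VTA (3.98 ± 0.80). Pdk3 was higher (3.86 ± 0.94) and Dkk3, a secreted Wnt modulator, lower (-5.87 ± 0.71) in VTA. Ttr was at 3025 ± 4132 in SNc against 3.43 ± 3.51 in NAc and 1.89 ± 2.81 in VTA. Snord118 had 0 reads in the 3 VTA libraries and 36.7 ± 5.18 in SNc, and Mir5616 had 0 reads in the 3 SNc libraries and 55.3 ± 57.7 in NAc. The SNc vs NAc count was 268 and 285 without NAc P30 replicates 1 and 2, and 125, 262 and 182 without SNc P30 replicates 1, 2 and 3. The VTA vs NAc count was 1671, 1539 and 1631 without NAc P30 replicates 1, 2 and 3 and 1004 without VTA P30 replicate 3, and on the deposited scale 28.2% of its genes were higher, against 3.6%. The VTA vs SNc count was 16, 80 and 5 without SNc P30 replicates 1, 2 and 3 and 262, 150 and 12 without VTA P30 replicates 1, 2 and 3, with 14 of the 262 and 4 of the 12 higher. Without VTA P30 replicate 3, 11.5% of the VTA vs NAc genes were higher.

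At P60, 471 genes (127 higher, 344 lower) differed between SNc and NAc, 737 genes (273 higher, 464 lower) between VTA and NAc and 2 genes (1 higher, 1 lower) between VTA and SNc, beside 645 at an unadjusted p under the threshold (n = 3 each). Crym, a thyroid hormone binding protein, was at 2.08 ± 2.10 in SNc, 1.17 ± 1.03 in VTA and 81.03 ± 48.03 in NAc. Cnih2, an auxiliary subunit of AMPA receptors, was lower in SNc than in NAc (-5.27 ± 0.65) and Gng7 lower in VTA (-4.82 ± 0.77). Tnf, tumor necrosis factor, was higher than in NAc in SNc (4.68 ± 1.23) and VTA (5.33 ± 1.23), calls lost in 5 and 3 of the 6 fits without a library. The small RNA gene Snora31 was higher in SNc (4.81 ± 0.74), and Mir1195 had 0 reads in the 3 NAc libraries and 50.4 ± 36.1 in VTA. Mbp was at 117 ± 26.6 in VTA and 1785 ± 422 in SNc (log2 fold change -3.92 ± 0.52, adjusted p = 0.00176). The share of higher genes in SNc vs NAc was 27%, against 13.4% and 40.1% without NAc P60 replicates 3 and 1 and 40.5% with a pseudocount of 0.1. In VTA vs NAc it was 37.0%, against 62.9% with a pseudocount of 0.1. The SNc vs NAc count was 255 and 158 without SNc P60 replicates 1 and 3, and the VTA vs NAc count 375, 393 and 327 without VTA P60 replicates 1, 2 and 3. The VTA vs SNc count was 1, 4 and 6 without SNc P60 replicates 1, 3 and 4, of which 0, 0 and 1 were higher. It was 9, 11 and 4 without VTA P60 replicates 1, 2 and 3, of which 7, 10 and 3 were higher.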

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

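The tests of row order, depth, microglial RNA, cell type shares, read numbers, the divisor, the added lists of microglial and macrophage states and the fit without 4 libraries with few detected genes or little 18S rRNA were chosen only after results were seen, while those of sequencing pool, starting molecules and splits were chosen before.

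Libraries of the dopaminergic sort had abundant microglial genes, while dopaminergic genes were low: Slc6a3 and Th had medians of 0.156 and 0.293, and Slc18a2, Ddc and Nr4a2, with 3 or more reads in most libraries, 1.84, 0.954 and 2.74. Rows out of register are excluded, because 4.06% of low values were whole reads with the length of the next row, against 100% with their own, and too little depth is excluded, because 3 reads of Slc6a3 give at most 0.13. RNA mostly from microglia is a candidate explanation: the microglia list, of whose 16 members 0 are in another fixed list, lay above the pan-neuronal and dopamine lists in 27 of 27 libraries, with C1qa at 487 to 9316 and Tyrobp at 223 to 3753. These levels restate the pattern and do not test where the RNA came from. In VTA P7 replicates 1, 2 and 3 the immature neuron list was at 6.751, 7.48 and 6.488 (median log2 values). There it lay above the microglia list, at 6.645, 6.561 and 6.398. A DAT sort gate should remove microglia, so the pattern may reflect cells that passed the gate or RNA carried with them, and no test separated these. No biological explanation was tested, since the design names no other cell type.

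Averaged over regions, cell cycle genes were lower and astrocyte, myelin and homeostatic microglial genes higher at both later ages than at P7, and endothelial genes at P60 (at P30 adjusted p = 0.0708 with an estimated correlation), but in NAc the homeostatic list was lower at P60 (6.36) than at P7 (7.56), and in VTA the astrocyte (4.82 to 4.21), myelin (2.02 to 0.654) and endothelial lists (1.59 to 0.85) were lower at P30 than at P7 (median log2 values). A change in the share of 1 main cell type alone would move the markers of all others alike, and is argued against by the blood list, whose median fell by 2.09 (in NAc it went from 2.43 to 3.27) while astrocyte, myelin and endothelial lists rose; this fall has an adjusted p of 0.0108, 0.287 with an estimated correlation and 0.0667 without the 4 libraries, and the immature neuron list fell too (adjusted p = 0.00215 with an estimated correlation). Without the 4 libraries (3711 genes, against 2883) the rises held but the share of higher genes grew, so few detected genes are not excluded. Pool and age cannot be told apart, since 0 ages shared a pool. Age itself, development of the cells, stays open and untested.

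VTA P30 replicate 3 had 6786 genes with a read. Fewer reads are excluded, because it kept 34.5% of the genes of the median library after all were thinned to the same depth. A wrong divisor alone is excluded, because its rank correlation with its group was at most 0.494. Few starting molecules remain a candidate explanation, because 22.7% of genes at 20 to 100 in the other VTA P30 libraries had 0 reads there. No biological explanation was tested.

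The effect of age differed between regions, by a test of the difference, for 2259 genes. The P60 vs P7 change differed for 174 genes between SNc and NAc, 2503 between VTA and NAc and 73 between VTA and SNc. The adjusted p of the interaction was 8.35e-05 for Ttr, 0.00011 for Ccnb1, 0.000262 for Dclk1, 0.000294 for Snhg11, 0.000348 for Arl11, Myt1l, Nrxn3 and Gnao1, and 0.000376 for Clip3. The log2 change from P7 to P60 in VTA minus that in NAc was -2.92 for Mbp, 6.19 for Tmem119, 5.29 for Selplg, 3.48 for Tpm3-rs7, 4.56 for Tlr2, -2.79 for Crmp1 and 5.31 for Ccl3. In SNc minus NAc it was 4.19 for Tmem119, 4.26 for Selplg and -5.45 for Nr4a2, and in VTA minus SNc it was -4.55 for Mbp.

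Lists whose P60 vs P7 change differed with an estimated correlation are given with the median difference of their members. In SNc minus NAc these were the cell cycle (1.26) and microglia and macrophage lists (2.00) upward. GABAergic (-2.11), glutamate receptor (-1.65), glutamatergic (-1.80), dopaminergic transcription factor (-1.05), neuropeptide (-1.96), pan-neuronal (-2.97), striatal projection neuron (-1.26), synaptic vesicle (-2.70) and ion channel lists (-1.51) differed downward. In VTA minus NAc the cell cycle (2.55) and microglia and macrophage lists (3.54) differed upward. GABA and glycine receptor (-2.60), GABAergic (-2.43), astrocyte (-3.28), glutamate receptor (-2.78), glutamatergic (-2.15), immature neuron (-2.79), mitochondrially encoded (-2.39), pan-neuronal (-4.04), synaptic vesicle (-3.94) and ion channel lists (-2.15) differed downward. In VTA minus SNc the astrocyte (-1.58) and myelin lists (-2.36) differed downward. Of the lists added after levels were seen, homeostatic microglia (4.23) differed upward in SNc minus NAc. In VTA minus SNc the MHC class I (2.24), axon tract microglia (2.16), border-associated macrophage (3.21), inflammatory (3.10) and interferon response lists (3.03) differed upward, with adjusted p = 0.0354 each with an estimated correlation, though at most 1 member of each passed.

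Of 100 splits of the same libraries, the real one included, 1 gave as many genes as the real split for P30 vs P7 (4464, highest other 144), P60 vs P30 (211, 189), P60 vs P7 (2883, 955), SNc vs NAc (255, 125) and the interaction (2259, 356). This share, under 0.05, argues against chance as their source, though for P60 vs P30 another split came close. For VTA vs NAc, 2 splits gave as many (368, 1917), a share also under 0.05. The 1917-gene split kept the regions apart at P7, exchanged them at P30 and mixed them at P60. This adds up differences that reverse with age, whose part was not tested. The synaptic vesicle list was at log2 4.97 in VTA and 3.55 in NAc at P7, but 0.86 and 3.80 at P30. The count alone is thus no evidence of a region effect shared by the ages. For VTA vs SNc, 5 of 100 gave as many (13, 42), so chance is not excluded.

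Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were, in this order, NAc P30 vs NAc P7 1811 and 4, NAc P60 vs NAc P30 497 and 26, NAc P60 vs NAc P7 1953 and 1, SNc P30 vs SNc P7 1249 and 2, SNc P60 vs SNc P30 14 and 1, SNc P60 vs SNc P7 720 and 3, VTA P30 vs VTA P7 3583 and 403, VTA P60 vs VTA P30 12 and 10, VTA P60 vs VTA P7 1885 and 5, SNc P7 vs NAc P7 96 and 6, VTA P7 vs NAc P7 1091 and 5, VTA P7 vs SNc P7 394 and 24, SNc P30 vs NAc P30 429 and 16, VTA P30 vs NAc P30 2629 and 14, VTA P30 vs SNc P30 51 and 45, SNc P60 vs NAc P60 471 and 13, VTA P60 vs NAc P60 737 and 6 and VTA P60 vs SNc P60 2 and 8.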

How the results depend on the processing

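The tests on the deposited scale, with voom on the recovered reads and without the 4 libraries were chosen only after results were seen. The other settings were chosen before the data were examined. Of 381 calls of genes chosen by the naming rule in the averaged comparisons, 322 were kept in all 27 fits without a library and 230 under all alternatives. The latter were 108 of 139 for P30 vs P7, 6 of 32 for P60 vs P30, 79 of 121 for P60 vs P7, 20 of 50 for SNc vs NAc, 17 of 36 for VTA vs NAc and 0 of 3 for VTA vs SNc. Of 64 in the comparisons of 2 groups, 50 were kept in all fits without a library. The counts of P30 vs P7 (3715 to 4820) and P60 vs P7 (2253 to 3975), averaged over regions, stayed within 1.5 times in these fits. Depth limits low genes: 3 reads of Slc6a3 give up to 0.13. In simulated data with 50 changed genes, P60 vs P7 averaged over regions recovered 0 at 2-fold, 4 at 4-fold, 16 at 8-fold and 27 at 16-fold, and NAc P60 vs NAc P7 0, 0, 3 and 11, so genes that did not pass may have changed, and without the 4 libraries the P60 vs P7 count was 3711. The tests planned for a table of counts were not run, because the table holds FPKM.

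Counts of genes that moved by over 1.5 times are given by setting, with the comparisons averaged over regions or ages first. With no filter except for genes at 0 in all libraries, the count was 21 for VTA vs SNc. Among genes with a mean of at least 5, the count was 2409 for P30 vs P7, 1598 for P60 vs P7, 117 for SNc vs NAc, 177 for VTA vs NAc, 0 for VTA vs SNc and 1170 for the interaction. With a pseudocount of 0.1, the count was 108 for SNc vs NAc, 195 for VTA vs NAc, 1 for VTA vs SNc and 1040 for the interaction, and 830 for NAc P30 vs NAc P7, 228 for NAc P60 vs NAc P30, 1015 for NAc P60 vs NAc P7, 793 for SNc P30 vs SNc P7, 6 for SNc P60 vs SNc P30, 389 for SNc P60 vs SNc P7, 65 for VTA P60 vs VTA P30, 1036 for VTA P60 vs VTA P7, 27 for SNc P7 vs NAc P7, 361 for VTA P7 vs NAc P7, 130 for VTA P7 vs SNc P7, 217 for SNc P30 vs NAc P30, 79 for SNc P60 vs NAc P60, 170 for VTA P60 vs NAc P60 and 1 for VTA P60 vs SNc P60. After quantile normalization, the count was 148 for VTA vs NAc. With only the compared libraries in the fit, the count was 56 for P60 vs P30, 548 for SNc vs NAc, 197 for VTA vs NAc and 1 for VTA vs SNc. On the deposited scale, the count was 192 for VTA vs NAc, and 118 for SNc P30 vs NAc P30, 1366 for VTA P30 vs NAc P30 and 12 for VTA P30 vs SNc P30. With voom and sample weights on the recovered reads, the count was 1377 for P60 vs P30, 5320 for P60 vs P7, 1675 for SNc vs NAc, 1414 for VTA vs NAc, 69 for VTA vs SNc and 6242 for the interaction, and 6438 for NAc P30 vs NAc P7, 999 for NAc P60 vs NAc P30, 4666 for NAc P60 vs NAc P7, 3270 for SNc P30 vs SNc P7, 136 for SNc P60 vs SNc P30, 4125 for SNc P60 vs SNc P7, 707 for VTA P60 vs VTA P30, 3010 for VTA P60 vs VTA P7, 2205 for SNc P7 vs NAc P7, 2894 for VTA P7 vs NAc P7, 921 for VTA P7 vs SNc P7, 905 for SNc P30 vs NAc P30, 83 for VTA P30 vs SNc P30, 1895 for SNc P60 vs NAc P60, 2633 for VTA P60 vs NAc P60 and 272 for VTA P60 vs SNc P60. Without the 4 libraries, the count was 599 for P60 vs P30, 575 for SNc vs NAc, 8 for VTA vs SNc and 3758 for the interaction. Nuclear oxidative phosphorylation genes in SNc vs NAc were not called (adjusted p = 0.975, median log2 fold change -0.18, 0 of 52 passed), and without the 4 libraries the list was called lower (adjusted p = 0.00704). Fixed lists also called only without these libraries were, for P30 vs P7, nuclear oxidative phosphorylation (higher, 0.0237) and sex-linked genes (lower, 0.0133), for VTA vs NAc GABA and glycine receptors (0.00337), GABAergic markers (0.0347) and ion channels (0.0149), all lower, and dopamine and ependymal genes (0.0294 each, higher), and for VTA vs SNc pan-neuronal genes (higher, 0.0455). With voom 44.6% of the genes were higher for SNc P60 vs SNc P7, against 27.9%, and 29.0% for VTA P30 vs VTA P7, against 11%. The majority turned to higher genes with a pseudocount of 0.1 for VTA P60 vs NAc P60 (107 of 170) and VTA P60 vs VTA P7 (524 of 1036), and to lower genes for VTA P7 vs NAc P7 (241 of 361). For these changes the cause was not tested, except that fewer genes or libraries enter the fits with a stricter filter, with only the compared libraries and without the 4 libraries.

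Replicate numbers do not appear to pair the libraries: of 25 pairs with the same number within an age, 3 had a correlation of residuals above 0.1 (-0.143 to 0.143), and of 23 within a region 1 (-0.142 to 0.101), and a library was closest to its own number in 17 of 50 and 19 of 46 cases. With the number as a block, the count was 45 for P60 vs P30, 1634 for P60 vs P7, 143 for SNc vs NAc, 169 for VTA vs NAc and 0 for VTA vs SNc, and 65 for NAc P60 vs NAc P30, 792 for NAc P60 vs NAc P7, 4 for SNc P60 vs SNc P30, 263 for SNc P60 vs SNc P7, 6 for VTA P60 vs VTA P30, 31 for VTA P30 vs SNc P30, 165 for VTA P60 vs NAc P60 and 8 for VTA P60 vs SNc P60. Of these genes 50.8% were higher for NAc P60 vs NAc P30 and 52.0% for NAc P60 vs NAc P7, against 34.2% and 42.5%. The cause was not tested.

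Without a library each, counts that moved by over 1.5 times ranged from 139 to 364 for P60 vs P30, 121 to 438 for SNc vs NAc, 206 to 569 for VTA vs NAc, 0 to 33 for VTA vs SNc, 824 to 1242 for NAc P30 vs NAc P7, 936 to 1748 for NAc P60 vs NAc P7, 43 to 69 for SNc P7 vs NAc P7, 390 to 1130 for VTA P7 vs NAc P7, 1308 to 2778 for the interaction, 288 to 622 for NAc P60 vs NAc P30, 125 to 319 for SNc P30 vs NAc P30, 1004 to 3177 for VTA P30 vs NAc P30, 158 to 559 for SNc P60 vs NAc P60, 327 to 704 for VTA P60 vs NAc P60, 682 to 1016 for SNc P30 vs SNc P7, 412 to 512 for SNc P60 vs SNc P7, 170 to 512 for VTA P7 vs SNc P7, 8 to 23 for SNc P60 vs SNc P30, 5 to 262 for VTA P30 vs SNc P30, 1 to 11 for VTA P60 vs SNc P60, 1185 to 1632 for VTA P60 vs VTA P7 and 9 to 130 for VTA P60 vs VTA P30. The cause was not tested.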

Other observations

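The lists of microglial and macrophage states and the tests on them were chosen only after levels of these genes were seen, and no explanation is offered for their values. From P7 to P60, averaged over regions, 9 of 12 homeostatic microglia genes rose (10 adjusted over the list alone), among them Gpr34 (4.27 ± 0.59; adjusted p = 0.0363 with an estimated correlation). Of 11 inflammatory chemokine and cytokine genes 9 fell, among them Il1b, interleukin 1 beta, from 122 ± 99.9 to 20.9 ± 35.2 (adjusted p = 0.043 with an estimated correlation). Of 12 genes of axon tract and proliferative-region microglia 6 fell, such as Spp1, osteopontin (-2.44 ± 0.59), Csf1 (-1.79 ± 0.40) and Lpl (-2.90 ± 0.39; adjusted p = 0.0363 with an estimated correlation). Of 10 border-associated macrophage genes 6 fell, such as Lyve1, from 94.6 ± 119 to 1.56 ± 2.38, and Pf4 (-3.25 ± 0.71; adjusted p = 0.000671, and adjusted p = 0.195 with an estimated correlation). In VTA the inflammatory list was at 6.79 ± 1.38 at P7 and 6.72 ± 0.61 at P60 (median log2 value, n = 3). Of 11 interferon response genes 2 fell. The list's median log2 fold change was 0.735 (adjusted p = 0.257, and 0.039 upward without the 4 libraries). Of 8 MHC class I genes, which share reads, 0 passed (adjusted p = 0.415).

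In SNc against NAc, averaged over ages, 2 of 11 inflammatory genes were higher (10 adjusted over the list alone; adjusted p = 0.00377 with an estimated correlation), 0 of 10 border-associated macrophage genes (7 adjusted over the list alone; adjusted p = 0.0236 with an estimated correlation) and 0 of 11 interferon response genes (3 adjusted over the list alone; adjusted p = 0.0155 with an estimated correlation). The border-associated macrophage list was at 6.70 ± 0.14 in SNc P7 (median log2 value, n = 3), against 3.13 ± 0.38 in NAc P7 and 2.71 ± 1.82 in VTA P7. The homeostatic list was at 7.56 ± 0.053 in NAc P7, 5.07 ± 0.067 in SNc P7 and 4.53 ± 0.26 in VTA P7, and at 6.36 ± 0.44, 8.18 ± 0.84 and 8.38 ± 0.60 at P60. The P60 vs P7 change of that list was higher in SNc than in NAc (median difference 4.23, 4 of 12 members passed; adjusted p = 0.0177 with an estimated correlation). In VTA against NAc the median difference was 5.00 and 9 of 12 passed, with an adjusted p = 1.08e-11, and adjusted p = 0.0584 with an estimated correlation. In VTA the axon tract list was at 3.29 at P7 and 3.52 at P60 (median log2 values), and at P30 the border-associated macrophage list was at 2.80 in SNc and 3.24 in NAc and the interferon list at 2.60 and 3.21.

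Cst3, cystatin C, was at 937 to 26427. Gapdh, a glycolytic gene with many pseudogene copies, was at 0 to 9.09, with 0 reads in 2 libraries, while Actb was at 1560 to 7266. Xist, expressed from the inactive X chromosome, was at most 0.301 and the Y-linked gene Ddx3y at 1.18 to 52.9 in the 27 libraries. Mitochondrial genes took 6.03 to 22.8% of the reads (median 11.3%), and the 10 most abundant genes of a library 11.8 to 29.7%.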
